A study of Mus musculus with 15 samples.

How the data were processed

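RNA sequencing of polyadenylated RNA had been done on mouse bone marrow cells of 2 kinds, bone marrow-derived macrophages (BMDM, 9 libraries) and BMSC (6 libraries), the latter named by that abbreviation in the labels. The authors deposited a single table of TPM (a length-corrected share, scaled to the same total, of each library's transcripts) for 56979 Ensembl gene identifiers, with 1 column per library. The submitters' processing notes name fastp, HISAT2, StringTie and RSEM and the genome build GRCm39, without versions, roles or the gene annotation. Each column summed to the same total within rounding, as TPM do, so the sequencing depth of each library is unknown, and no counting interval or detection floor is given for any value.

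Symbols were taken from a name table that matched 52072 of the 56979 identifiers and left 4907 without a symbol. That table belongs to an older build than the deposited values, so no coordinates are given. Groups followed the sample names, with 3 libraries in each of 5 groups. The labels number the libraries of a group but do not say whether they are separate animals, separate cultures or repeated libraries, and they do not pair them.

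Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), and figures were drawn with Python 3.11.15. A gene was tested when its TPM reached at least 1 in at least 3 of the libraries in the fit. The 9 BMDM libraries were fitted together, and the 6 BMSC libraries were fitted together. A fit of all 15 libraries, Control included, tested the difference between the NZM responses of the cell types. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called changed at an adjusted p under 0.05. On this scale the pseudocount of 1 makes the change of a low gene smaller than its fold in TPM.

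Gene lists were written before the data were examined and tested with camera of limma at its preset correlation of 0.01 between genes, where at least 5 members were tested, with adjustment over the lists of a comparison. They comprised 47 usable lists, of which 9 held markers of cell types. The preset is lenient for genes that are regulated together, so the lists were also tested with a correlation estimated from the data and with fry, which asks whether the members of a list move, on balance, in a single direction and compares them with no other genes. Genes named in the text were chosen by a rule written beforehand. It took the 6 largest rises and the 6 largest falls among called genes without overlap between the groups and with a mean of at least 5 TPM in the higher group, leaving out predicted genes without a regular symbol, up to 4 members per list with the largest changes, and a fixed set of genes reported whatever their values. For the difference between the NZM responses it took the 5 largest in each direction. Genes chosen after their values were seen are named as such.

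TPM are shares of a whole, so a rise of a few abundant transcripts lowers the share of all others. Each comparison was therefore repeated after centring every library on the median of its tested genes, and counts are given on both scales where they part. Other alternatives were a pseudocount of 0.1, no filter, a TPM of at least 5, quantile normalization, removal of mitochondrially encoded genes, no mean-variance trend, weights per library, a block for the replicate number, other sets of libraries in the fit, a minimum absolute log2 change of 1, and leaving out each library in turn. The procedure was tested on simulated data with 200 changed genes of different sizes, and of those given a log2 change of 1, 88.1% to 94.0% were recovered across the 4 comparisons of groups, with 3.74% to 6.63% of calls false. No library was left out of the main results.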

Results

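Gene expression was measured in 15 libraries of mouse bone marrow cells. The BMDM, macrophages grown from bone marrow, comprised Control (vehicle), LPS and LPS_NZM. LPS is lipopolysaccharide, a component of the bacterial outer membrane that activates macrophages. The BMSC comprised Aged, labelled with the treatment H2HO, and Aged_NZM, labelled H2HO with NZM. The labels state that both cell types received NZM after pretreatment with model drugs, and they explain neither NZM nor H2HO. Each group held 3 libraries, and values are mean TPM ± SD over these 3 unless stated otherwise. Between 21360 and 23398 identifiers had a TPM above 0 in a library, and the depth behind them is unknown. P-values measure only the spread between these libraries, which may be technical, since the labels do not say what a replicate is. BMDM given NZM without LPS and BMSC without H2HO were not analysed here.

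The comparison of LPS with Control shows the response of the BMDM libraries to the model drug. These libraries also held transcripts of other cell types, such as Col1a1 at 1303 TPM and the neutrophil marker Ngp at 681.3 TPM in Control. A change in them therefore cannot be assigned to macrophages alone. The largest rise was that of Il1b (ENSMUSG00000027398), which encodes the cytokine interleukin-1 beta, from 12.6 ± 18.5 TPM in Control to 5523 ± 77.7 TPM in LPS (log2 change 9.77, SE 0.82, adjusted p = 1.63e-06). Nos2 (ENSMUSG00000020826), the inducible nitric oxide synthase, rose from 1.52 ± 2.38 to 685.1 ± 36.4 TPM, and Acod1, which makes itaconate, reached 4867 ± 58.8 TPM from 15.9 ± 18.3 TPM. The chemokine genes Cxcl10 and Cxcl1 and the cytokine gene Il1a also rose, by log2 changes of 8.23, 7.74 and 8.24. Among the largest falls were Nfatc2, a transcription factor of the NFAT family (33.6 ± 1.42 to 0.76 ± 0.132 TPM), Gcnt1, Susd3, Rab3il1, Hip1 and Pdxk, with log2 changes from -4.63 to -3.93. The large relative SD of Il1b, Acod1 and Nos2 in Control came from Control replicate 3. Il1b read 2.77, 0.94 and 33.9 TPM in the 3 Control libraries, and Nos2 read 0.12, 0.17 and 4.27 TPM. Il1a (1.62, 0.65 and 6.53 TPM) and Il6 (0.91, 1.69 and 4.64 TPM) were also highest in Control replicate 3. Without Control replicate 3 the log2 changes were 10.996 for Il1b, 9.59 for Acod1, 9.23 for Nos2 and 8.86 for Cxcl10, against 9.77, 8.72, 8.49 and 8.23 with it.

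Of the genes fixed for reporting, Tnf (1421 ± 3.38 against 40.2 ± 2.53 TPM), Il6 (629 ± 34.0 against 2.41 ± 1.97 TPM), Il10, Ccl2, Cd86, Nlrp3, Nfkbia, Sod2 and Hmox1 were higher with LPS. Mrc1, the mannose receptor used as a marker of alternatively activated macrophages, fell from 249.7 ± 3.87 to 78.0 ± 3.19 TPM. Arg1, the arginase often used as a marker of the same state, read 28.2 ± 2.68 TPM in LPS and 28.4 ± 8.85 TPM in Control (log2 change 0.04, adjusted p = 0.859). Its call depended on a library and on the scale, with a log2 change of -0.23 (adjusted p = 0.025) without Control replicate 2 and 0.58 (adjusted p = 0.0233) after median centring.

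In groups, 18 of 19 tested inflammatory cytokines rose and none fell, and all 20 NF-kB feedback regulators rose, among them Nfkbia, Socs3 (12.2 ± 3.24 to 1138 ± 8.22 TPM) and Traf1. All 30 interferon-stimulated genes rose as well, including Rsad2, which encodes an antiviral enzyme, and the guanylate-binding protein gene Gbp5, whose reads may be shared with related copies. Of 20 chemokines 17 rose and 1 fell (adjusted p = 0.0637 with an estimated correlation). Of 19 genes of inflammatory (M1-like) activation 18 rose and 1 fell (adjusted p = 0.0823 with an estimated correlation), and Saa3, an acute-phase protein gene, went from 83.8 ± 33.0 to 10170 ± 323 TPM. The list of senescence-associated secreted factors, which shares cytokine genes with the lists already given, had 21 risen and 6 fallen members of 33. The M2-like list split, with 6 of 19 risen and 9 fallen, or 11 risen and 8 fallen after centring, and it did not pass (adjusted p = 0.256). Its falling members included the scavenger receptor genes Cd163 and Stab1 and the lectin gene Clec10a. Lists of markers of other cell types were called as higher too. Neutrophil markers had 6 of 14 risen and 3 fallen (adjusted p = 0.339 with an estimated correlation). Dendritic cell markers had 2 of 6 risen and none fallen (adjusted p = 0.108 with an estimated correlation), with Ccr7 at 21.7 against 1.46 TPM. Mast cell and basophil markers had 2 of 10 risen and none fallen (adjusted p = 0.396 with an estimated correlation). Among the latter Hdc read 76.0 against 4.34 TPM. The means of Cpa3, Mcpt4, Tpsb2, Fcer1a and Ms4a2 were lower in LPS, without a call. Whether these calls reflect more such cells or changed expression within the macrophages was not tested.

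Metabolic and housekeeping groups moved as well. Of 19 glycolysis genes 12 rose and 6 fell (adjusted p = 0.147 with an estimated correlation), with Pfkfb3, a regulator of glycolytic flux, at 1742 ± 36.0 against 64.4 ± 5.68 TPM, and the glucose transporter gene Slc2a1 at 145 ± 6.93 against 48.4 ± 1.60 TPM. NRF2 antioxidant targets were divided, with 12 of 24 risen and 10 fallen, or 19 risen and 3 fallen after centring. The cystine transporter gene Slc7a11 was the largest riser among them (log2 change 5.46). All 27 DNA repair genes fell, 20 of them also after centring, when none rose (adjusted p = 0.161 with an estimated correlation). Among them Parp1, which encodes a sensor of DNA breaks, went from 107.8 ± 3.35 to 24.7 ± 0.835 TPM. Of 34 proliferation genes 29 fell, but after centring 14 fell and 8 rose (adjusted p = 0.396 with an estimated correlation), and the replication factors Mcm2 and Cdt1 were among the falls. Of 29 lysosome genes 25 fell, but after centring 14 fell and 9 rose (adjusted p = 0.317 with an estimated correlation). Ribosomal protein genes turned with the scale, since 29 of 33 fell as deposited and 30 rose after centring.

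In all, 11705 of 14486 tested genes changed, 2203 up and 9502 down, and 3516 changed at least 2-fold on the log2(TPM + 1) scale. The median log2 change over tested genes was -0.48, and after centring 9494 changed, 5285 up and 4209 down, so that the share of changes that were rises went from 18.8% to 55.7%. Falls smaller than the median shift are therefore not separable from a shift of the TPM scale, whose cause was not tested. With camera 21 of 46 lists were called, 16 up and 5 down. The calls that held with an estimated correlation were the 6 rises of inflammatory cytokines (adjusted p = 0.0392), NF-kB feedback regulators (adjusted p = 0.0281), interferon-stimulated genes (adjusted p = 0.0392), inflammasome genes (adjusted p = 0.0392), NRF2 targets (adjusted p = 0.0415) and senescence-associated secreted factors (adjusted p = 0.0415). Adjusted over the list alone, the counts of risen and fallen members were the same in 43 of the 46 lists and differed by at most 1 gene in the others.

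The comparison of LPS_NZM with LPS asks what NZM changed in LPS-treated BMDM libraries, with the same limit on the cell types behind a change. Most inflammatory transcripts were lower with NZM. Nos2 fell from 685.1 ± 36.4 to 4.66 ± 1.34 TPM (log2 change -6.95, SE 0.49, adjusted p = 4.78e-07), Cxcl10 from 4872 ± 88.9 to 52.3 ± 10.6 TPM, and Il12b, a subunit gene of interleukin-12, from 192.5 ± 5.04 to 1.28 ± 0.266 TPM. Saa3, Rsad2 and the chemokine gene Ccl5 completed the 6 largest falls, with log2 changes of -6.09, -5.99 and -5.93. Arg1 (ENSMUSG00000019987) rose most, from 28.2 ± 2.68 to 2959 ± 39.0 TPM (log2 change 6.67, SE 0.19, adjusted p = 4.16e-10). Retnla (ENSMUSG00000061100), a secreted marker of alternative activation, rose from 0.783 ± 0.276 to 164.5 ± 9.63 TPM, and the transcription factor gene Egr2 from 4.01 ± 0.231 to 216.1 ± 6.58 TPM. The lectin gene Mgl2, B3gnt7 and Tmem26 rose by log2 changes of 5.28, 5.94 and 5.26.

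Among the fixed genes Il6 (629 ± 34.0 to 9.55 ± 1.29 TPM), Il1b (5523 ± 77.7 to 149.9 ± 3.72 TPM), Tnf (1421 ± 3.38 to 177.9 ± 3.56 TPM), Il10, Cd86, Nlrp3, Nfkbia, Sod2 and Hmox1 fell. Mrc1 rose from 78.0 ± 3.19 to 1411 ± 49.2 TPM. Ccl2, a monocyte-attracting chemokine gene, read 985.4 ± 32.9 TPM with NZM and 863.8 ± 41.5 TPM without it, a log2 change of 0.19 (adjusted p = 0.00733) that turned to -0.27 (adjusted p = 0.00119) after median centring.

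**Figure D1:**
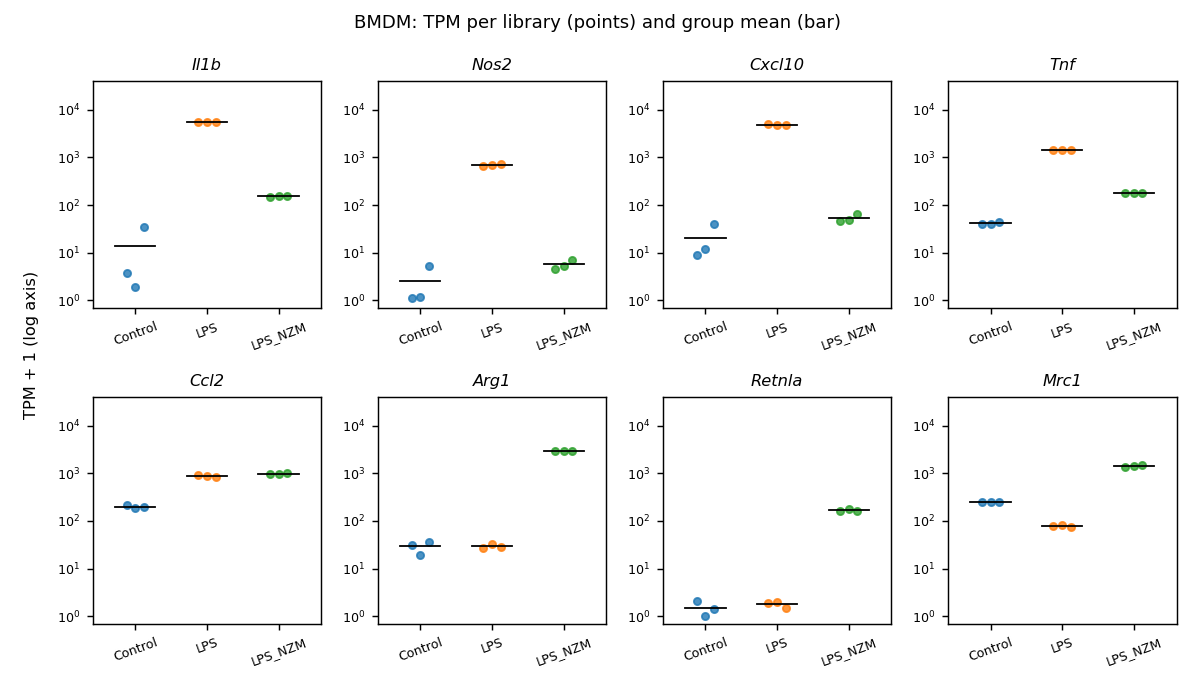
TPM + 1 on a log axis for 8 genes in the 3 BMDM groups, with a point per library and a bar at the group mean. Il1b, Nos2, Cxcl10 and Tnf were high in LPS and lower in LPS_NZM, Control replicate 3 lay above the other Control libraries for Il1b, Nos2 and Cxcl10, and Arg1 (2959 TPM), Retnla (164.5 TPM) and Mrc1 (1411 TPM) were highest in LPS_NZM; the small difference of Ccl2 between LPS and LPS_NZM turned with median centring.

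All 30 interferon-stimulated genes and all 20 NF-kB feedback regulators fell with NZM, on both scales, with Gbp5 going from 856.4 ± 1.38 to 13.8 ± 2.46 TPM and Socs3 from 1138 ± 8.22 to 47.1 ± 1.96 TPM. Of 19 inflammatory cytokines 17 fell and 1 rose (adjusted p = 0.0724 with an estimated correlation), and of 20 chemokines 13 fell and 4 rose (adjusted p = 0.202 with an estimated correlation). Of 19 M1-like genes 18 fell and 1 rose (adjusted p = 0.157 with an estimated correlation). The M2-like list went the other way, with 16 of 19 risen and 2 fallen, or 14 and 4 after centring (camera adjusted p = 0.014, adjusted p = 0.2 with an estimated correlation). Besides Arg1, Retnla, Egr2 and Mgl2, the risers of other lists included Clec7a, the beta-glucan receptor gene (68.8 ± 2.36 to 1093 ± 15.3 TPM), and Pparg, a nuclear receptor of lipid metabolism (4.92 ± 0.517 to 58.4 ± 1.49 TPM).

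NRF2 targets fell in 15 of 24 cases and rose in 6, or fell in 20 and rose in 2 after centring. Slc7a11 went from 394.1 ± 3.58 to 14.5 ± 1.51 TPM, the glutathione reductase gene Gsr from 417.5 ± 10.1 to 85.4 ± 1.94 TPM, and Txnrd1, thioredoxin reductase, from 782.2 ± 11.9 to 259.2 ± 8.19 TPM. Of 19 glycolysis genes 12 fell and 6 rose, or 14 fell and 1 rose after centring (adjusted p = 0.198 with an estimated correlation), and Pfkfb3 returned to 56.8 ± 4.81 TPM. Of 20 hypoxia and HIF targets 12 fell and 5 rose (adjusted p = 0.182 with an estimated correlation), Hif1a itself among the falls. Of 21 TCA cycle genes 19 rose and 1 fell, or 11 and 3 after centring (adjusted p = 0.233 with an estimated correlation), with Idh2 at 100.7 ± 1.40 against 34.7 ± 0.574 TPM. DNA repair genes rose in 26 of 27 cases, and 13 rose and none fell after centring (adjusted p = 0.233 with an estimated correlation). Of 29 lysosome genes 26 rose, a direction that was not kept after centring, when 11 rose and 9 fell (adjusted p = 0.233 with an estimated correlation). All 33 ribosomal protein genes rose as deposited, and 11 rose and 2 fell after centring (adjusted p = 0.523 with an estimated correlation). Class II antigen presentation genes rose in 10 of 11 cases, led by H2-DMa, but after centring 4 rose and 4 fell, and the list did not pass (adjusted p = 0.0989).

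In all 11197 of 14486 genes changed, 8752 up and 2445 down, with 3232 changed at least 2-fold. The median log2 change was 0.40, and centring gave 4310 up and 5118 down, so that rises went from 78.2% to 45.7% of the changes. Camera called 23 of 46 lists, 8 up and 15 down. Among lists of markers of other cell types, that of mast cells and basophils was called as falling, with 2 of 10 fallen and none risen (adjusted p = 0.523 with an estimated correlation). Its member Hdc read 5.92 TPM in LPS_NZM against 76.0 TPM in LPS. With an estimated correlation 4 lists held, namely the falls of NF-kB feedback regulators (adjusted p = 0.0266), NRF2 targets (adjusted p = 0.0266), interferon-stimulated genes (adjusted p = 0.0437) and inflammasome genes (adjusted p = 0.0437). Adjusted over the list alone, 43 of the 46 lists had the same counts, and the others differed by at most 1 gene. The iron handling and osteoclast lists were called as falling (adjusted p = 0.302 and adjusted p = 0.233 with an estimated correlation) although the median change of their members was 0.18 and 0.10, which is above 0 and less than the median shift. In LPS against Control the osteoclast list was called as rising (adjusted p = 0.161 with an estimated correlation) with a median of -0.02.

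Most genes that LPS had changed moved back when NZM was present. Of the 11705 genes changed by LPS, 9939 changed in the opposite direction in LPS_NZM against LPS, or 84.9% (Wilson 95% interval 84.3% to 85.5%, over genes, which are not independent), and 270 moved further. The return was not complete, since 6160 (52.6%) still differed from Control, and 2248 lay on the other side of Control, changed against both groups. Centring lowered the share to 76.7%. The share was 85.5% for genes that rose with LPS and 84.8% for genes that fell. Of 3516 genes changed at least 2-fold, 3368 moved back, and the median fraction of the LPS change that was undone was 0.864. Because both changes share the LPS libraries, their errors are linked. The changes had opposite signs, called or not, in 94.9% of the LPS-changed genes. In 20 simulated sets where LPS_NZM did not differ from LPS that share averaged 51.9%, and the correlation across genes averaged -0.0858, against a measured Pearson r of -0.865 and Spearman rho of -0.821 across genes. By list, all 29 interferon-stimulated genes and all 20 NF-kB feedback regulators changed at least 2-fold by LPS moved back, with median fractions undone of 1.14 and 0.671, though 26 and 19 of them still differed from Control. Among chemokines 13 of 17 moved back, and among senescence-associated secreted factors 18 of 20. Their median fractions undone were 0.711 and 0.672, and 14 and 15 of them still differed from Control.

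**Figure D2:**
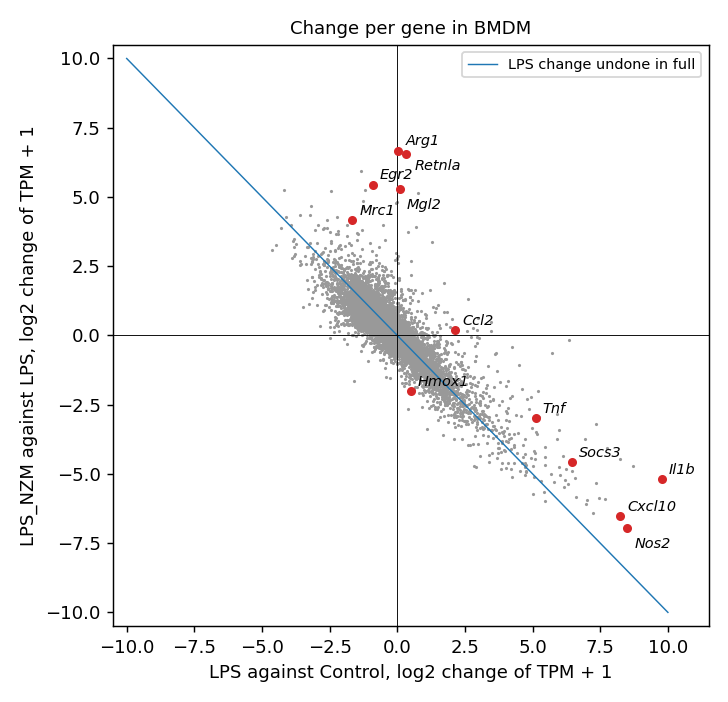
Log2 change of TPM + 1 per gene in LPS against Control (horizontal) and in LPS_NZM against LPS (vertical), with a grey point per tested gene and the named genes in red; the line marks a change undone in full. Points follow the line with a Pearson r of -0.865 across genes, of which shared LPS libraries alone gave -0.0858 in simulated sets, while Arg1, Retnla, Egr2, Mgl2 and Mrc1 lie above it; the vertical change of Ccl2 turned with median centring.

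The comparison of LPS_NZM with Control shows what remained different. Residual inflammatory expression was present, with Il1b at 149.9 ± 3.72 against 12.6 ± 18.5 TPM (log2 change 4.57, or 5.80 without Control replicate 3), Tnf at 177.9 ± 3.56 against 40.2 ± 2.53 TPM (log2 change 2.12, adjusted p = 1.85e-10) and Nfkbia at 215.9 ± 1.71 against 91.6 ± 2.43 TPM. Of 20 NF-kB feedback regulators 18 were higher and 1 lower than in Control (adjusted p = 0.0566 with an estimated correlation), and of 20 chemokines 15 were higher and 1 lower (adjusted p = 0.245 with an estimated correlation). Interferon-stimulated genes were below Control in 21 of 30 cases and above it in 6 (camera adjusted p = 0.000375, adjusted p = 0.38 with an estimated correlation). Of 19 M2-like genes 13 were higher and 5 lower (adjusted p = 0.0571 with an estimated correlation), with Arg1 at 2959 ± 39.0 against 28.4 ± 8.85 TPM. Hmox1, the heme oxygenase gene, was lower than in Control at 915.6 ± 10.7 against 2637 ± 5.01 TPM. Other NRF2 targets followed, 17 of 24 in the list being lower and 2 higher, or 14 and 2 after centring (adjusted p = 0.0566 with an estimated correlation). Class II presentation genes were higher in 9 of 11 cases and lower in none (adjusted p = 0.0571 with an estimated correlation). The call of Nos2 as higher than in Control (log2 change 1.54, adjusted p = 0.0271) was lost under 7 alternatives, with adjusted p from 0.0532 to 0.0997 and log2 changes that stayed between 1.16 and 1.58. Without Control replicate 3, the highest of the Control libraries for Nos2, the call was kept, with a log2 change of 2.28 (adjusted p = 4.56e-06). They included leaving out Control replicate 1 (adjusted p = 0.0918), Control replicate 2 (adjusted p = 0.0997), LPS_NZM replicate 2 (adjusted p = 0.0581) or LPS_NZM replicate 3 (adjusted p = 0.0823) for Nos2.

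In this comparison 6915 of 14486 genes changed, 2697 up and 4218 down, or 3612 up and 3190 down after centring, with 651 changed at least 2-fold and a median shift of -0.07. Camera called 23 of 46 lists and none held with an estimated correlation, while 24 had an unadjusted camera p under 0.05 and fry called 40. Adjusted over the list alone, 35 of the 46 lists had the same counts, and the others differed by at most 3 genes. Markers of neutrophils were higher in LPS_NZM than in Control in 10 of 14 cases and lower in none (adjusted p = 0.248 with an estimated correlation), with S100a9 at 779 ± 92.0 against 447.8 ± 70.8 TPM.

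The comparison of Aged_NZM with Aged asks what NZM changed in BMSC pretreated with H2HO. Several extracellular matrix genes were among those that rose. Thbs2, thrombospondin 2, went from 714.9 ± 36.1 to 3911 ± 46.6 TPM (log2 change 2.45, SE 0.04, adjusted p = 3.35e-10), the collagen genes Col1a1 (ENSMUSG00000001506) from 308.8 ± 18.3 to 863.2 ± 35.2 TPM and Col1a2 from 436.2 ± 18.7 to 1526 ± 13.6 TPM, and Sparc from 864.3 ± 32.2 to 2637 ± 43.1 TPM. Cxcl12, the chemokine that retains blood stem cells in marrow, rose from 127.9 ± 1.25 to 679.3 ± 5.13 TPM. Saa3 became the most abundant transcript of the Aged_NZM libraries, at 18870 ± 328 against 3504 ± 253 TPM, and Lcn2, lipocalin 2, rose from 631.7 ± 9.51 to 1457 ± 8.59 TPM. The largest rises by rule were those of Clca3a2 (1.88 ± 0.118 to 64.9 ± 1.53 TPM), Angptl7, mt-Co3, Ccn5, Saa2 and Scg2, of which mt-Co3 owes its place to Aged replicate 3, where it read 0.26 TPM against 98.7 and 94.2 TPM in the other Aged libraries, and without which its log2 change was 1.82 instead of 3.91. The largest falls were those of the glutathione transferase gene Gsta1 (31.3 ± 1.43 to 0.667 ± 0.0379 TPM), Prl2c3 (3991 ± 27.6 to 268.5 ± 6.46 TPM), Ccr1, Lilr4b, Bcl2l15 and Upp1.

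Genes of the cell cycle arrest programme parted. Cdkn1a (ENSMUSG00000023067), which encodes the inhibitor p21, fell from 203.6 ± 8.62 to 49.6 ± 2.75 TPM (log2 change -2.02, SE 0.05, adjusted p = 2.19e-09), whereas Cdkn2a (ENSMUSG00000044303), which encodes p16 and p19Arf, rose from 267.4 ± 9.12 to 677.4 ± 20.9 TPM, and Cdkn2b rose as well. Gene-level values do not separate the p16 and p19Arf transcripts. Trp53 fell from 67.7 ± 2.75 to 47.5 ± 1.76 TPM, and of 25 p53 targets 18 fell and 4 rose, a list that did not pass (adjusted p = 0.0798). The chromatin protein genes Hmga2 (298.1 ± 5.32 to 44.1 ± 2.29 TPM) and Hmga1 and the deacetylase gene Sirt1 (20.8 ± 0.652 to 10.3 ± 0.98 TPM) also fell. Lmnb1, lamin B1, read 27.5 ± 0.735 TPM with NZM and 29.7 ± 1.65 TPM without (adjusted p = 0.105), a result that passed without Aged replicate 1 (adjusted p = 0.0432) or with weights per library (adjusted p = 0.03). Of 19 senescence regulators 11 fell and 6 rose (adjusted p = 0.784). Of 30 senescence-associated secreted factors 16 rose and 13 fell (adjusted p = 0.0569), with Mmp3 rising and Mmp10 and Plaur falling, and Il6 rose from 87.5 ± 2.05 to 159.7 ± 9.66 TPM.

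**Figure D3:**
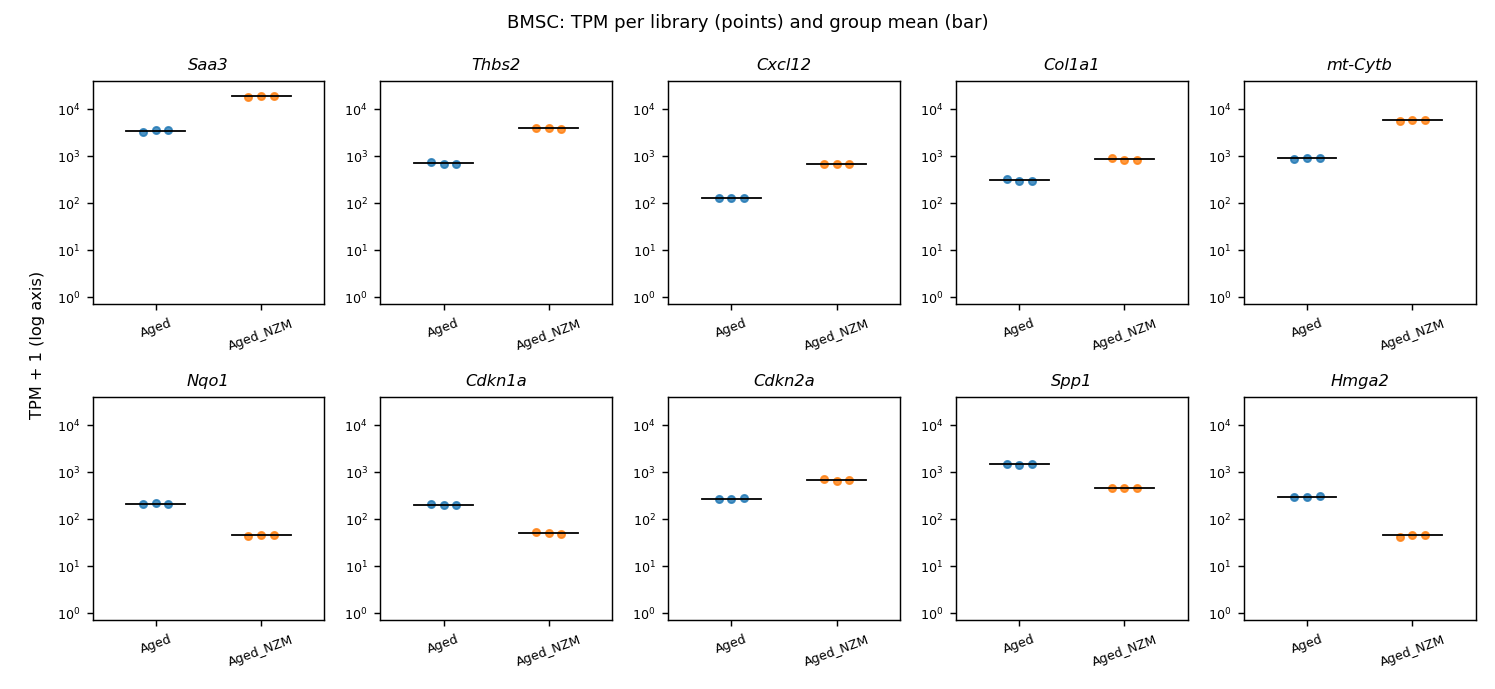
TPM + 1 on a log axis for 10 genes in the BMSC groups, with a point per library and a bar at the group mean. Saa3, Thbs2, Cxcl12, Col1a1, mt-Cytb and Cdkn2a were higher in Aged_NZM, and Nqo1, Cdkn1a, Spp1 and Hmga2 were lower, on the deposited scale and after median centring.

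All 29 extracellular matrix genes rose, on both scales (camera adjusted p = 5.59e-22, adjusted p = 0.211 with an estimated correlation). All 14 markers of stromal cells and fibroblasts rose too (adjusted p = 0.185 with an estimated correlation), among them Acta2, smooth muscle actin (301.2 ± 6.31 to 1147 ± 34.0 TPM), Tagln and Pdgfrb. These lists share Col1a1, Col1a2, Col3a1, Dcn, Lum, Postn, Fbn1 and Fn1. Of 15 progenitor and niche markers 10 rose and 3 fell (adjusted p = 0.338 with an estimated correlation). Osteogenic genes rose in 7 of 13 cases and fell in 3 (adjusted p = 0.322 with an estimated correlation). Alpl, alkaline phosphatase, rose from 4.02 ± 0.652 to 11.8 ± 0.443 TPM, while Spp1, osteopontin, fell from 1463 ± 18.4 to 463.1 ± 4.01 TPM. Runx2, the osteoblast transcription factor gene, read 60.1 ± 2.97 against 56.3 ± 3.07 TPM (adjusted p = 0.137) and passed after median centring (adjusted p = 0.00116) or without Aged replicate 1 (Runx2 adjusted p = 0.0334), and Sp7 and Bglap were too low to be tested in BMSC.

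NRF2 target genes mostly fell, and peroxide and superoxide enzymes went both ways, with 8 of 20 risen and 9 fallen, or 8 and 7 after centring (adjusted p = 0.528). Of 24 NRF2 targets 20 fell and 3 rose, or 17 and 4 after centring (camera adjusted p = 0.00373, adjusted p = 0.185 with an estimated correlation), with Nqo1 (ENSMUSG00000003849), a quinone reductase, going from 212.4 ± 2.81 to 44.5 ± 1.20 TPM, Hmox1 from 1091 ± 29.3 to 737.3 ± 16.3 TPM, and Slc7a11 and Gsta4 falling too. The catalase gene Cat fell from 102.3 ± 3.87 to 75.6 ± 1.27 TPM, and Sod2, the mitochondrial superoxide dismutase, rose from 102.2 ± 0.436 to 163 ± 2.07 TPM. Of 15 heat shock genes 11 fell and 1 rose (adjusted p = 0.322 with an estimated correlation), with the chaperonin gene Hspd1 at 218 ± 5.18 against 509.8 ± 7.09 TPM. Of 28 unfolded protein and integrated stress response genes 17 fell and 9 rose (adjusted p = 0.356), with Asns, Trib3 and Chac1 among the falls. All 13 mitochondrially encoded genes of the list rose (adjusted p = 0.185 with an estimated correlation), mt-Cytb from 898.7 ± 35.8 to 5950 ± 157 TPM. All identifiers with a mitochondrial symbol, transfer RNA genes included, made up 3.94% to 4.25% of TPM in Aged_NZM libraries against 1.40% to 1.47% in Aged. Values of mt-Co3 (374.6 ± 202 against 64.4 ± 55.6 TPM) were scattered, and its call (adjusted p = 0.0319) was lost under 6 alternatives, with adjusted p from 0.05 to 0.131 and log2 changes that stayed between 3.50 and 4.52, among them leaving out Aged_NZM replicate 1, 2 or 3 (mt-Co3 adjusted p = 0.0568, adjusted p = 0.051 and adjusted p = 0.0864). Genes of the nuclear part of oxidative phosphorylation did not pass as a list (adjusted p = 0.987), with 6 of 32 risen and 15 fallen, or 13 risen and 8 fallen after centring.

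Of 28 DNA repair genes 22 fell and 2 rose, or 17 and 4 after centring (adjusted p = 0.338 with an estimated correlation), with Chek1 and Atm, both checkpoint kinase genes, at log2 changes of -1.03 and -0.84. Proliferation genes divided, with 19 of 34 risen and 13 fallen (adjusted p = 0.494 with an estimated correlation). The mitotic genes Ccnb2 (9.79 ± 1.33 to 28.2 ± 3.51 TPM) and Ube2c rose, and the replication gene Mcm2 fell from 160.9 ± 6.52 to 72.3 ± 0.947 TPM. Ribosomal protein genes fell in 28 of 33 cases and in 17 after centring, with no rise on either scale (adjusted p = 0.338 with an estimated correlation). Of 11 chemokines 8 rose and 1 fell (adjusted p = 0.185 with an estimated correlation), of 27 interferon-stimulated genes 12 rose and 5 fell (adjusted p = 0.188 with an estimated correlation), with Ifi47 at 11.4 ± 0.642 against 4.03 ± 0.533 TPM, and of 19 glycolysis genes 12 rose and 4 fell (adjusted p = 0.584 with an estimated correlation). In all 9774 of 13865 genes changed, 2999 up and 6775 down, or 4318 up and 4907 down after centring, with 1089 changed at least 2-fold and a median shift of -0.18. Camera called 13 of 37 lists, 9 up and 4 down, and none held with an estimated correlation, while 18 had an unadjusted camera p under 0.05 and fry called 31. Adjusted over the list alone, 30 of the 37 lists had the same counts, and the others differed by at most 2 genes.

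**Figure D4:**
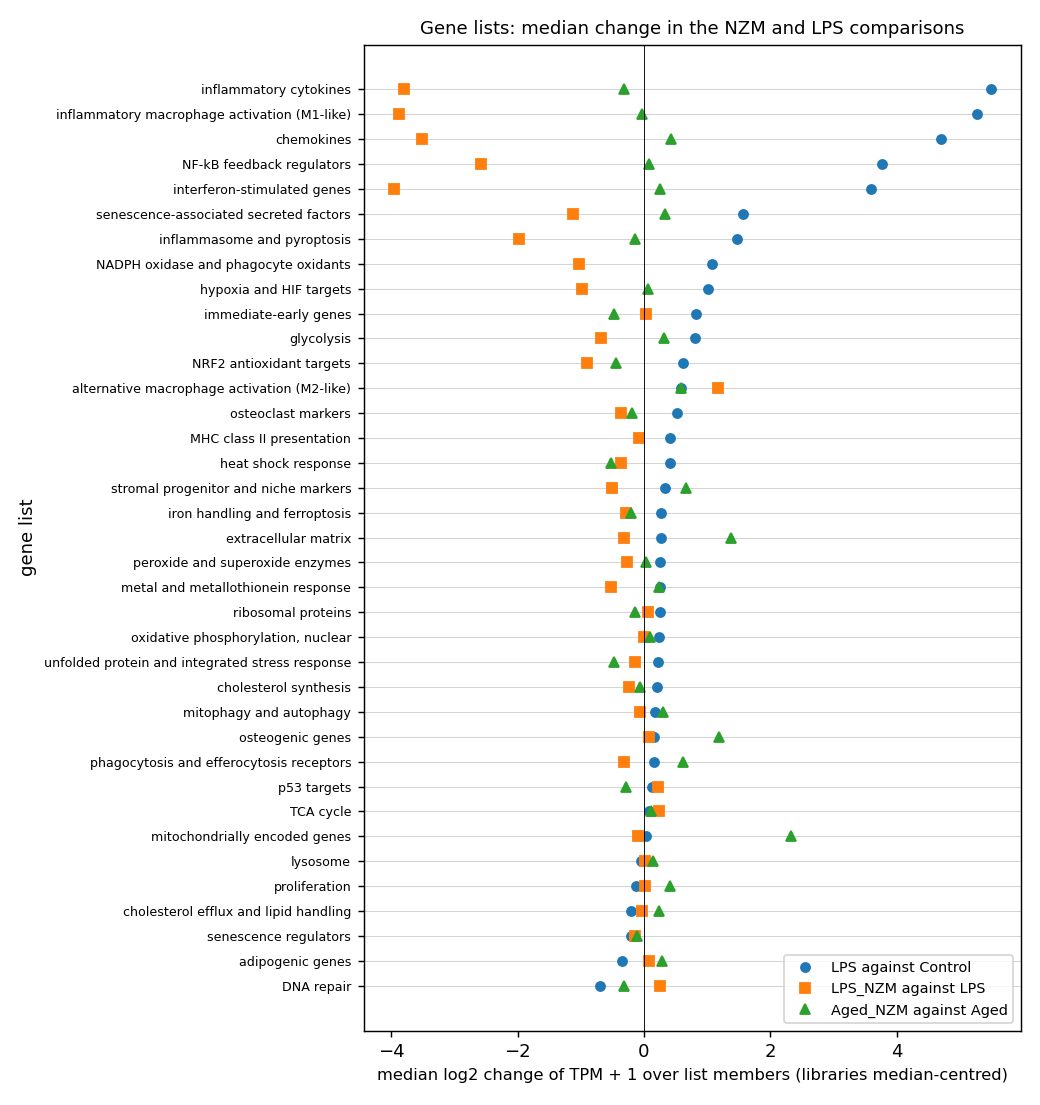
Median log2 change of TPM + 1 over the tested members of each list, after centring each library on its median, in 3 comparisons (circles, squares and triangles). Inflammatory cytokines had centred medians of 5.49 in LPS against Control, -3.80 in LPS_NZM against LPS and -0.32 in Aged_NZM against Aged, and mitochondrially encoded genes had a centred median of 2.33 in BMSC; on the deposited scale most lists near 0 lie lower in the first comparison and higher in the second.

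The NZM responses of the cell types were set side by side across 11703 genes tested in both. The antioxidant transporter gene Slc7a11 fell in both, by log2 changes of -4.68 in BMDM and -1.95 in BMSC, and so did Plaur, Upp1 and Mmp10, examples chosen after their values were seen. Saa3, Steap4, Lcn2, Mmp3 and Ifi47 fell in BMDM and rose in BMSC, and Mcm2, Cdt1 and Hspd1 rose in BMDM and fell in BMSC. Of 7359 genes called in both, 2343 changed in the same direction (31.8%) and 5016 in opposite directions. Rises in both numbered 1503, below the 1718 that independent lists would share (odds ratio 0.629, Fisher's exact p = 1.2e-23, over genes that are not independent), and falls in both numbered 840 against 958.4 (odds ratio 0.734, p = 1.47e-09 by the same exact test). After centring 2401 of 5804 changed in the same direction, 985 up and 1416 down, and these too were fewer than independent lists would share, 1241 and 1572. The changes correlated weakly across the 11703 genes, with a Pearson r of -0.127 and a Spearman rho of -0.155, and genes are not independent replicates. At 2-fold in both cell types 76 genes changed in the same direction and 199 in opposite directions. The cell types were pretreated with different model drugs, so a difference between them cannot be assigned to either. The Y-linked gene Eif2s3y read 61.3 ± 3.98 TPM in Control BMDM and was listed at 0 in all BMSC libraries, which leaves the sex or origin of the cells, and the presence of identifiers in the table, confounded with cell type.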

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

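The tests of annotation and of cell type for identifiers absent from the BMDM libraries, the restriction to identifiers above 0 in both cell types and the split with the BMSC groups exchanged were chosen only after the result was seen; the test of the difference and the splits of the samples were not.

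The response to NZM differed between BMSC and BMDM in 12020 of 16696 tested genes, which drew attention as a difference between groups. It was tested directly as the difference of the changes (BMSC minus BMDM, 3 libraries per group). The filter ran over all 15 libraries, whereas 11703 genes passed it in both cell types. The count thus includes genes barely expressed in a cell type, where the difference is mostly the change in the other. The share among the 11703 was not computed. The difference was positive in 2876 genes and negative in 9144, or 6663 and 4786 after median centring, with a median shift of -0.45. The largest positive difference by the naming rule was that of Saa3 (log2 difference 8.52, adjusted p = 8.17e-13), which fell from 10170 to 149.1 TPM with NZM in BMDM and rose from 3504 to 18870 TPM in BMSC. Steap4, a metalloreductase gene, followed with 7.05 (28.6 to 0.73 TPM and 25.4 to 203.7 TPM), and Il6 with 6.76 (629 to 9.55 TPM and 87.5 to 159.7 TPM). Gbp5 (6.65) and Cxcl10 (6.64) fell in BMDM from 856.4 and 4872 TPM and stayed low in BMSC, at 0.707 and 1.91 TPM for Gbp5 and at 9.82 and 10.6 TPM for Cxcl10.

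The negative differences of largest size were those of Arg1 (-6.89), Retnla (-6.55), Egr2 (-6.05), B3gnt7 (-5.96) and Cd300lb (-5.72). Each rose in BMDM, Arg1 from 28.2 to 2959 TPM and Cd300lb from 22.5 to 601.7 TPM, and was listed at low values or at 0 in BMSC, where Arg1 read 0.237 and 0.05 TPM and Retnla was listed at 0 in both groups. A value of 0 need not be low expression. In all, 261 named identifiers with a mean of at least 5 TPM in BMDM were at 0 in all BMSC libraries. Whether all of them were quantified there is unknown. Cd300lb fell in BMSC, from 2.36 to 0.64 TPM (log2 change -1.03, adjusted p = 5.03e-05). Cell type, model drug, quantification and the sex or origin of the cells are confounded, so the difference can be assigned to none of them. Camera called 22 of 47 lists for the difference, 16 up and 6 down, of which 9 held with an estimated correlation, all as higher. These were the inflammatory cytokines, NF-kB feedback regulators, interferon-stimulated genes, inflammasome genes, NADPH oxidase genes, mitochondrially encoded genes, extracellular matrix genes, progenitor and niche markers, and markers of stromal cells. NRF2 targets and phagocytosis receptors were called as higher (adjusted p = 0.0727 and adjusted p = 0.119 with an estimated correlation) although their mean differences were -0.13 and -0.03 (medians 0.10 and 0.12).

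In 100 drawn splits of the libraries 1 gave as many genes, the real one (real value 12020, highest other 8391). The other drawn splits mix NZM and no-NZM libraries in BMSC, in BMDM or in both. Mixing leaves only part of the NZM change between the groups there and adds the rest to the spread within them. Such splits give fewer genes whether or not the responses differ, so they do not decide whether the difference arose by chance. The split with the BMSC groups exchanged, which was not drawn, gave 10695 genes. Of the other drawn splits, the 6 that kept the real groups in BMDM alone gave 7045 to 8391 genes, the 12 that kept them in BMSC alone gave 2122 to 2983, and the 81 that kept neither gave at most 7. For genes changed by NZM in the same direction in both cell types, 1 of 100 drawn splits gave as many, the real one (real value 2343, highest other 0), but this says nothing about chance, since mixed splits call next to no genes and so share none. The split with the BMSC groups exchanged, which was not drawn, gave 5016 such genes, above the real 2343.

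Part of the difference between the cell types lies in the identifiers themselves. Of 80 identifiers newer than the name table with a mean of at least 5 TPM in BMSC, 77 were at 0 in all 9 BMDM libraries. Newer identifiers above 0 were 17.9 times as many in the 6 BMSC libraries (1254) as in 6 BMDM libraries (70), whereas the same ratio was 1.02 for identifiers in the name table (28084 and 27627). In the other direction 261 named identifiers had a mean of at least 5 TPM in BMDM and were at 0 in all BMSC libraries, against 47 the other way, and they include macrophage genes, pseudogenes and mitochondrial transfer RNAs such as mt-Tl1 (357.8 TPM in Control). A cell type difference in expression would be expected to touch both classes, and the ratio of 1.02 argues against it as the whole cause. The ratio of 17.9 is consistent with gene annotations that differed between the BMSC and the BMDM quantification, and a difference in library preparation, which the absent transfer RNAs also raise, stays open. With only identifiers above 0 in both cell types, 11490 genes differed in their NZM response, so identifiers at 0 throughout a cell type carry a small part of the count. That restriction asks for a value above 0 in only a single library of each cell type, so genes near 0 in a cell type remain.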

How the results depend on the processing

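Lists with median centring and the difference with only identifiers above 0 in both cell types were chosen after seeing the data; the other choices and alternatives were made before the data were examined. Of 2745 values of 163 gene results over 26 settings, 2723 kept direction and side of the threshold, 13 lost the call, 7 gained it and 2 reversed. The reversals were those of Arg1 in LPS against Control (-0.23 without Control replicate 2, up to 0.22 without Control replicate 3 among single libraries left out, and 0.58 with median centring) and Ccl2 in LPS_NZM against LPS (-0.27 with median centring). Centring moves all changes of a comparison by the same amount, which turned the small change of Ccl2. Leaving out Control replicate 2 takes out the lowest Control value of Arg1, 18.6 TPM against 30.7 and 35.8 TPM. Why that library was low for Arg1 was not tested. A minimum absolute log2 change of 1 left 3516, 3232, 651 and 1089 genes in LPS against Control, LPS_NZM against LPS, LPS_NZM against Control and Aged_NZM against Aged, 5520 for the difference, 76 changed in the same direction in both cell types and 65.6% moved back, since it asks for larger changes. Lists called in LPS against Control, LPS_NZM against LPS and Aged_NZM against Aged numbered 6, 4 and 0 with an estimated correlation, and 45, 46 and 31 with fry, which asks another question. The share moved back was 79.0% with no filter, 88.6% with a TPM of at least 5, 80.2% with quantile normalization and 76.7% with median centring; the cause was not tested.

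Other settings kept the counts of genes within 1.5 times, from 9494 (median centring) to 12517 (no filter) in LPS against Control. Leaving out each library in turn gave 11148 to 11485, 10567 to 10761, 5887 to 6470 and 9047 to 9302 genes in the 4 comparisons, 11645 to 11842 for the difference, 2156 to 2317 in both cell types and 82.1% to 87.0% moved back; lists ranged from 20 to 22, 22 to 23 and 13 to 17. Median centring of the lists gave 19, 17 and 11. A block for the replicate number, which the labels do not call a pairing, gave 11683, 11089, 6681 and 9688 genes. Depth is unknown for TPM, so what it limits for low genes could not be computed.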

Other observations

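The tests of Control replicate 3 and of genes beyond both other groups were chosen only after the result was seen; the splits of the samples were not.

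The BMDM libraries held transcripts of other cell types. All 14 stromal cell and fibroblast markers reached at least 1 TPM in Control BMDM (median 196 TPM, against 193 TPM in Aged BMSC). Col1a1 at 1303 ± 60.6 TPM and Sparc, outside that list, at 2320 ± 49.8 TPM lay above the 308.8 and 864.3 TPM of Aged BMSC. Other markers of the list were lower in Control BMDM than in Aged BMSC, such as Dcn (90.9 against 1509 TPM), Pdgfra (6.01 against 91.4 TPM) and Fn1 (620 against 1265 TPM). Sp7, an osteoblast transcription factor gene, read 8.90 TPM in Control BMDM and 0.0867 TPM in Aged BMSC, and Postn 184.7 and 1.54 TPM. Of 14 neutrophil markers 13 reached 1 TPM in Control, with Ngp at 681.3 TPM and S100a9 at 447.8 TPM, as did all 10 mast cell and basophil markers, among which Cpa3 was scattered (149.5 ± 168 TPM). In Aged BMSC macrophage markers had a median of 0.0567 TPM against 937 TPM in Control BMDM, with Lyz2 at 2.80 and 22620 TPM. Nos2 was expressed in BMSC, at 75.3 ± 3.74 TPM in Aged and 51.1 ± 1.81 TPM in Aged_NZM.

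Interferon-stimulated Ifit3, chosen after its values were seen, read 239.3 ± 11.6 TPM in Control, 1810 ± 19.2 TPM in LPS and 67 ± 1.87 TPM in LPS_NZM, below both. Genes with other such patterns, also chosen after their values were seen, were Pid1 (75.4 TPM against 479.2 in LPS and 365.7 in Control), Klra2 (4.64 against 57.2 and 25.8) and Calcrl (12.2 against 157.2 and 47.6). Above both lay Pdcd1lg2, an inhibitory immune ligand gene (78.1 TPM against 1.24 and 0.32), and Clec10a (140.4 against 2.81 and 19.98).

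At least 2-fold beyond both LPS and Control were 273 genes of LPS_NZM, 210 above and 63 below. A smaller LPS response would leave each gene between Control and LPS, and simulated sets of that kind gave at most 6 such genes in 20 sets, so the 273 genes argue against it as the whole cause. After median centring there were 249, 192 above and 57 below. The median log2 shifts were 0.40 against LPS and -0.07 against Control, less than the 2-fold asked for. A shift of the TPM scale of that size could not alone produce these genes, so that centring adds little as a test. Of the 19 tested M2-like genes 10 were above both groups (odds ratio 79.1, Fisher's exact p = 2.73e-14, over genes that are not independent). They are 10 of the 210 genes above both. The test was chosen after Arg1, Retnla, Egr2 and Mgl2 had been seen among the largest rises. It therefore describes part of the pattern, a shift toward genes of alternative activation, and does not explain it. Without BMDM given NZM alone, whether the pattern needs LPS stays open.

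Control replicate 3 lay above the mean of Control replicates 1 and 2 in 34 of 35 genes with at least 100 TPM in LPS and at least 50-fold above that mean, a choice of genes that itself favours an excess in replicate 3. The excess had a median of 0.59% of the LPS level, with quartiles of 0.513% and 0.742%, a ratio of 1.45, while the excess of LPS_NZM over the same genes spread from 1.32% to 5.84%. A nearly constant share is consistent with a small amount of LPS material in Control replicate 3, although the bound set for the ratio of 1.45 was 1.5 and so was nearly reached. Weak activation of those cells cannot be told apart from it by the 34 genes, since both raise them. Library or sequencing carry-over was not tested separately.

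For comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05, and 1 of 10, the real one, gave a result as large in each. The real values and the highest of the other splits were 11705 and 1 genes in LPS against Control, 11197 and 0 in LPS_NZM against LPS, 6915 and 2 in LPS_NZM against Control, and 9774 and 0 in Aged_NZM against Aged. The share moved back was 84.9%, and the 0% of the other splits says nothing about chance, since those splits call no genes in LPS_NZM against LPS. For lists they were 21 and 20, 23 and 18, and 13 and 8 in LPS against Control, LPS_NZM against LPS and Aged_NZM against Aged. Mixed splits thus also called lists. With 3 libraries per group no mixed split is even, so each keeps part of the real change, which lists that move together can still show. These list counts therefore do not decide whether the list calls arose by chance.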
